A study of Arabidopsis thaliana with 2 samples.

How the data were processed

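Total RNA of complete rosettes, harvested 25 days after germination, was measured in 1 wild-type sample and 1 TCP15-EAR sample. Per the labels' protocols, the plants grew on soil at 22 to 24 °C with 16 h of light at about 100 µE, RNA was prepared with a column kit and labelled with Cy3. Samples were grouped by the genotype in the labels.

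Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.3.1, which gives for each spot an intensity on a linear scale (mean, median, background and processed signal, with an error) and flags for outliers, saturation and signal well above background. The deposited value table holds 1 log2 value per probe and array; how the authors normalized it is not given in the sources used here. Its columns had medians of 9.10 each, and their sorted values differed by at most 0.11, as after a quantile normalization. The TCP15-EAR column rose with a slope of 0.94 on the log2 background-subtracted median signal, hence the log2 scale, with no centring of genes and no ratio. For the wild-type column these properties could not be set against an array. Each array had 43803 spots of non-control probes, 50 probes having 5 spots each. The median processed signal was 753.3 on the array labelled wild type and 362.7 on the TCP15-EAR array, and the median coefficient of variation between spots of a probe 6.20% and 3.78%.

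For the scanner comparison, control spots and spots with an outlier flag on either array (87 and 12 flags) were left out. The log2 processed signal minus each array's 75th percentile was averaged over the spots of a probe. A gene's ratio was the mean over its probes well above background on both arrays, TCP15-EAR minus wild type. A gene with a probe well above background on 1 array and with none on the other has only a bound: its bright level minus the higher of the dim probe's level and the lowest level among probes well above background.

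The mismatch between the wild-type scanner file and the wild-type column was seen after the data were examined. The value table, planned as an alternative, was then also analysed as a comparison of its own. The table has no flags, so a probe counted as measured above 5.84, the 99th percentile of the TCP15-EAR column over probes not well above background on that array. Of the probes well above background there, 2.67% lay at or below this level. The same level served for bounds. Probes with outlier flags were kept, since the table holds them. Both comparisons use the same TCP15-EAR array and are not independent.

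Of 43513 probes without flags, 35784 were assigned to 1 locus, 34094 of them through their transcript accession and 1690 through the gene name in the files; 449 matched several loci and were not used for genes, and 7280 had none. Symbols came from a RefSeq gene table of the assembly TAIR10.1, from which no coordinates were taken, since the array design names another build. Probes of a gene were averaged; among 6247 genes with several measured probes in the value table, the median gap between the highest and lowest log2 ratio was 0.15.

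The 24 gene lists with 440 genes, the ribosomal protein lists defined by description, the settings and the rule for named genes were fixed before the data were examined. The rule names TCP15, the 12 highest and 12 lowest ratios among genes at or above the median level whose probes move the same way, of each list the genes with the 2 highest and 2 lowest ratios past 2-fold (otherwise the 2 largest in size), and the 4 largest bounds in each direction among genes with a symbol. It was followed for the value table, except that 1 gene it selects is not reported here. For the scanner files, list members were named only for 9 lists, which departs from the rule. Lists of pollen, tapetum, CBF target, morning clock and evening clock genes were added after the data were examined. Each list is described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean level in 10 bins. A list is said to lie above or below the random lists past percentiles 97.5 and 2.5. This describes these arrays and is no test between genotypes; p-values were not computed. A planned list of genes with class I TCP sites was not analysed here, since it needs a genome.

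Alternatives were normexp background correction (offset 50), quantile, loess (span 0.4) and median normalization, no filter or a stricter filter on dim probes, the brightest probe of each gene, outlier flags kept, the value table on the same probes, and random lists without matching. Those for the value table were chosen after its data were seen. The steps were tested on simulated data for the value table comparison: 200 of 20427 genes were changed, with noise of 0.20 (SD, log2), the scanner's own error alone. All genes changed by 1.5 or 3 (log2) passed 2-fold (100%), with 0 false calls, which noise this small makes certain and which says nothing of differences between plants, and of 200 random sets of unchanged genes 6.5% lay outside the random lists' range, where 5% would by construction. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used.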

Results

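Transcript levels were measured in complete rosettes of Arabidopsis thaliana (ecotype Col-0) collected 25 days after germination. Wild-type plants were compared with plants that carry TCP15 fused to the EAR motif and expressed from the TCP15 promoter. TCP15 is a class I TCP transcription factor, and the EAR motif is a short plant repression domain that turns an activator into a repressor. Each genotype was represented by 1 array of a one-colour (Cy3) Agilent design with 43603 distinct probes, so there were no replicates and the comparison rests on sizes alone. Both arrays lay on the same slide. Of the probe spots, 81.5% were well above background on the array labelled wild type and 78.6% on the TCP15-EAR array, and no spot was saturated on either. The scanner's own error amounted to 0.20 (log2) on the ratio of a gene such as LHCA2 in the scanner files. It covers the reading of the spots and not differences between plants. For the value table, the error of the TCP15-EAR array stood in for both columns, so no reading error of the wild-type column is known.

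The scanner file labelled wild type and the wild-type column of the authors' value table ordered the probes differently. Across 43553 probes with a single spot, the TCP15-EAR column of the value table had a Spearman rank correlation of 1 with the background-subtracted median signal of its own scanner file. The wild-type column reached at most 0.917 with any signal of the scanner file labelled wild type, and 0.976 with the TCP15-EAR scanner file. Floral organ genes set the files apart: after each was set to its 75th percentile, their median level was 1.205 (log2) in the scanner file labelled wild type and -3.45 in that of TCP15-EAR. In the value table it was -3.51 in the wild-type column and -3.07 in the TCP15-EAR column. Both comparisons are therefore given, the planned one from the scanner files and that from the value table. Of 49 named gene ratios of the scanner files, 17 changed direction with the wild-type measurement used. A further 31 moved by more than the scanner's error and 1 stayed the same. These genes were named mostly for large ratios. Across genes, the ratios of both comparisons had a Pearson correlation of 0.27.

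**Figure D1:**
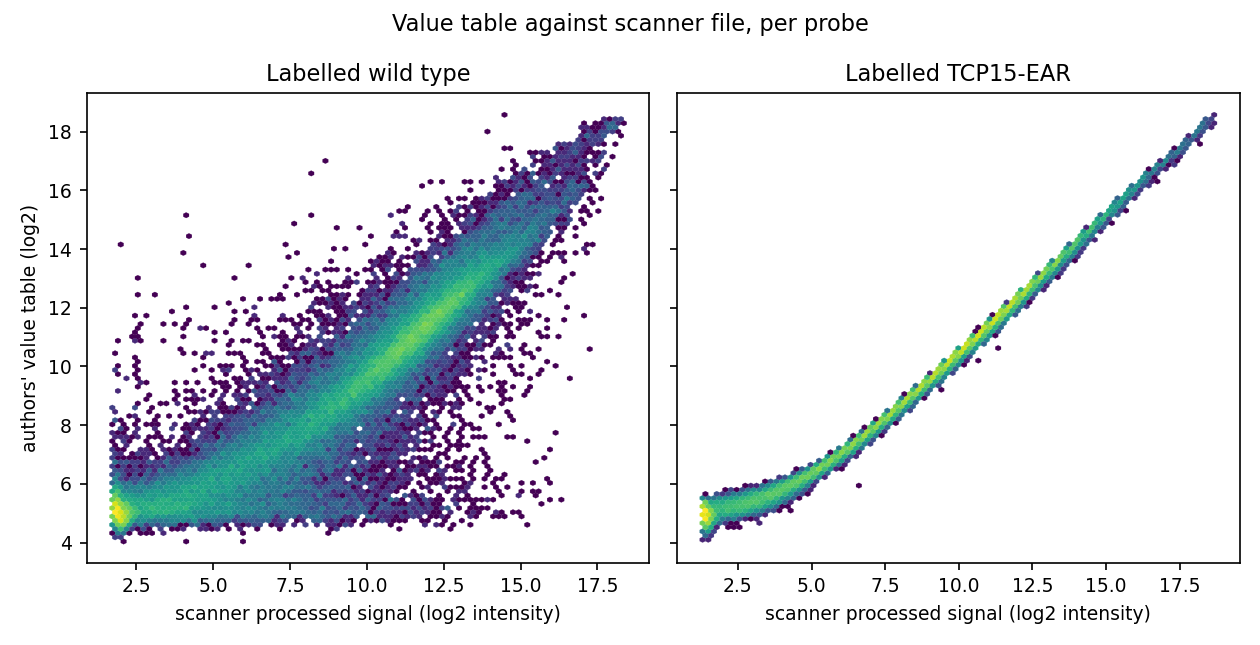
Value of each probe in the authors' table (log2) against its processed scanner signal (log2 intensity), for the array labelled wild type (left) and TCP15-EAR (right), with lighter cells holding more probes on a log colour scale. The TCP15-EAR probes fall on a single curve, which flattens at low signal, whereas the wild-type probes scatter widely around theirs.

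TCP15 itself was read by 3 probes that did not move together. The probe at transcript position 1154 (chromosome 1, 26217378 to 26217437 in the build named by the array design, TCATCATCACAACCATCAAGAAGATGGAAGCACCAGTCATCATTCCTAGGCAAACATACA) was higher in TCP15-EAR, with a log2 ratio of 2.17 or 4.49-fold in the value table and 1.27 in the scanner files. The probe at transcript position 1474 (26217698 to 26217757, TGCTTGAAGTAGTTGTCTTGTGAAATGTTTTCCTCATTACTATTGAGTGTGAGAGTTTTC) was lower, with log2 ratios of -1.10 and -0.93. The former sequence has 2 reading frames free of stop codons and the latter has 0. The remaining frame of the former reads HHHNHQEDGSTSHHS and then a stop. Which frame encodes TCP15 was not identified, so open frames do not place the former probe wholly within the coding part. Which parts the transgene shares was not settled here without a genome. The remaining probe was designed on an expressed sequence tag, has coordinates that run the other way and was dim; its log2 ratios were 0.63 and 1.52. The mean over the probes, the planned value for the gene, was 0.62 in the scanner files and 0.56 in the value table. It hides opposite directions: the brightest probe alone gave 1.27 in the scanner files, and leaving out the expressed sequence tag gave 0.17.

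In the planned comparison of the scanner files, genes of flowers and pollen were far lower on the TCP15-EAR array than on the array labelled wild type. Genotype and flower content of the samples therefore cannot be told apart in this comparison. This holds for all its gene ratios, counts and list medians. PI and AP3, which specify petals and stamens, had log2 ratios of -7.26 and -5.91, SEP2 (AT3G02310) -7.12 and AP1, a floral meristem identity gene, -5.87. GRP17 and GRP19, oleosins of the pollen coat, were not well above background on the TCP15-EAR array and were brighter on the other by at least 3207-fold and 2145-fold, as were the pectin enzyme genes PGA4 (at least 2996-fold) and VGD1 (at least 2102-fold). Some genes of photosynthetic tissue were far higher. LHB1B1, a light-harvesting protein, had a log2 ratio of 5.31, the plastid glutamine synthetase GS2 5.15 and RbcX1, a chaperone of Rubisco assembly, 6.52. The probes of GS2 lay far apart, at 1.07 and 9.23, and those of LHB1B1 ran from 2.05 to 7.35, so their means stand for no single probe.

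Of 20905 genes measured on both arrays, 2605 were at least 2-fold higher and 2996 at least 2-fold lower in TCP15-EAR. Only a bound was had for 503 genes brighter in TCP15-EAR and 1587 brighter on the other array. It reached 2-fold for 337 and 1172 of them. The authors' value table on the same probes gave 1173 higher and 863 lower, with 57.6% of these genes higher against 46.5% in the scanner files. The share also passed 50% without the value table, at 52.6% with normexp correction, 53.7% with quantile normalization, 52.1% with median normalization and 59.7% with the stricter filter. Among genes at or above the median level whose probes moved the same way, the remaining ones with the largest positive ratios were AT3G05730 (8.08), BT2 (7.74), AT4G34290 (90.5-fold), UGT72E1 (5.87), AT1G49500 (5.58), RAV2 (5.42), GSTF2 (5.38), IGMT4 (5.19) and the clock gene PRR5 (5.13). Within the same limits, the largest remaining negative ratios were those of AT3G49540 (-8.03), AT5G22430 (-8.02), BAM5 (-7.10), AT2G20870 (-6.78), the arabinogalactan protein gene AGP6 (-6.77), the senescence gene SAG12 (-6.53), MIF2 (-5.98) and AT1G10770 (-5.90). In the other direction, PDF1.2, a defensin, was brighter in TCP15-EAR by at least 1329-fold, RAV1 by at least 634-fold, CLC-B by at least 421-fold and SCL21 by at least 402-fold.

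All 14 floral organ markers were lower in the scanner files, 13 of them at least 2-fold, with a median log2 ratio of -4.43, at percentile 0 of the random lists. Photosynthesis genes were higher for 29 of 30 (median 1.60, percentile 100) and glucosinolate genes for 22 of 23 (median 1.98, percentile 100). Of the 26 lists, 13 lay above and 8 below the random lists. Above them were also cold, drought and abscisic acid (1.41), the circadian clock (1.32), root markers (1.28), salicylic acid and defence (1.26, with PR1 at 7.78 and BGL2 at 5.03), touch and wounding (percentile 100, with 8 of 12 at least 2-fold higher), senescence (1.02), the anthocyanin and flavonoid pathway (0.77, although 8 of 22 genes were at least 2-fold lower against 11 higher), organellar ribosomal proteins (0.72), heat shock (0.68), SAUR (0.48) and the TCP family (0.45). Below them were also jasmonate (-0.83), organ boundary and KNOX genes (-0.80), cell wall loosening (-0.79), mitotic cell cycle (-0.72), DNA replication (-0.55), flowering time (-0.53) and cytosolic ribosomal proteins (-0.18). Auxin response (-0.31), auxin synthesis and transport (0.11), cytokinin (-0.53), gibberellin (0.13) and iron supply (0.60) lay inside the range. Opposite directions met within several of these lists. Of 18 SAUR genes 8 were at least 2-fold higher, SAUR24 (1.87) and SAUR23 (1.78) foremost, and AT1G29490 was lower (-3.08). Among cytokinin genes CKX4 (3.05) and IPT3 (1.76) were higher and CKX3 (-2.78) and RR16 (-1.66) lower. Among senescence genes SEN1 (2.35) and NAC042 (1.76) were higher and SAG29 (-5.62) lower, and in defence PBS3 (-2.18) and WRKY18 (-1.22) were lower. Among TCP genes TCP5 (2.06) and AT5G08330 (1.76) were higher and TCP1 (-1.26) and TCP9 (-1.16) lower. AT5G08330 stands as TCP21 in the fixed list, whereas the gene table used for symbols calls it TCP11. LHCA2 (2.31) was among the 24 photosynthesis genes at least 2-fold higher, with LHCB4.3 lower (-3.34), and IMS2 (3.75) and MYB51 (3.19) among 17 glucosinolate genes. Root markers gave PYK10 (4.88) and NRT2:1 (3.301) higher and SHV2 (-4.03) lower. Some of these ratios rest on a dim, though measured, level on 1 array. That level (log2) was -7.10 for CKX4 and -7.03 for PR1 on the array labelled wild type. On the TCP15-EAR array it was -7.26 for AT1G29490 and -7.02 for SHV2. The medians of floral markers, photosynthesis and SAUR had the opposite sign in the value table.

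In the value table, genes of anthocyanin synthesis were strongly higher in TCP15-EAR and most of the listed SAUR genes were lower. DFR, which makes leucoanthocyanidins, was 70.7-fold higher (log2 ratio 6.14), UF3GT, a glycosyltransferase, 56.4-fold higher (5.82), and GSTF12, needed to move anthocyanins into the vacuole, had a log2 ratio of 4.28. Of the 18 listed SAUR genes, which respond quickly to auxin during cell expansion, 17 were measured, and 14 of these were at least 2-fold lower, led by AT1G29450 (-2.43) and AT1G29500 (-2.29). Photosynthesis genes had small ratios, with a median log2 ratio of -0.10 over 30 genes, but only 4 of the 30 were above 0.

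Of 20427 genes above the background level of the table in both columns, 989 were at least 2-fold higher and 852 at least 2-fold lower in TCP15-EAR. Counting only genes in the brighter part of the table left 376 higher and 354 lower among 11830. Among genes at or above the table's median level whose probes moved the same way, the largest remaining positive ratios were those of AT4G22870, annotated as a putative leucoanthocyanidin dioxygenase (5.46), the cell wall enzyme gene XTH15 (4.53), ATIM (4.51), AT4G27657 (4.42), the jacalin lectin gene AT1G52100 (4.09), the peptide transporter PTR3 (3.74), AT1G36060 (3.62), AT4G27652 (3.58), AT3G29000 (3.54) and CBF1 (3.47). Under the same limits, AT1G14250 (-3.58), the thionin gene AT1G66100 (-3.31), AT4G02850 (-2.91), MSRB6 (-2.91), SAUR29 (-2.90), AT5G03120 (-2.71), the arabinogalactan protein genes AGP4 (-2.68) and FLA9 (-2.49), VSP1 (-2.57), AT5G01015 (-2.47) and the pectate lyase gene AT5G63180 (-2.36) had the largest remaining negative ratios. A further 619 genes brighter in TCP15-EAR and 586 brighter in wild type had only a bound, which reached 2-fold for 151 and 98 of them. GILT was higher in TCP15-EAR by at least 45.0-fold, DD11 by at least 36.9-fold, FLA5 by at least 11.5-fold and PRR2 by at least 9.62-fold. MEE48 was brighter in wild type by at least 9.38-fold, ACOS5 by at least 8.51-fold, BSMT1 by at least 7.65-fold and CYP703A2 by at least 6.94-fold.

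**Figure D2:**
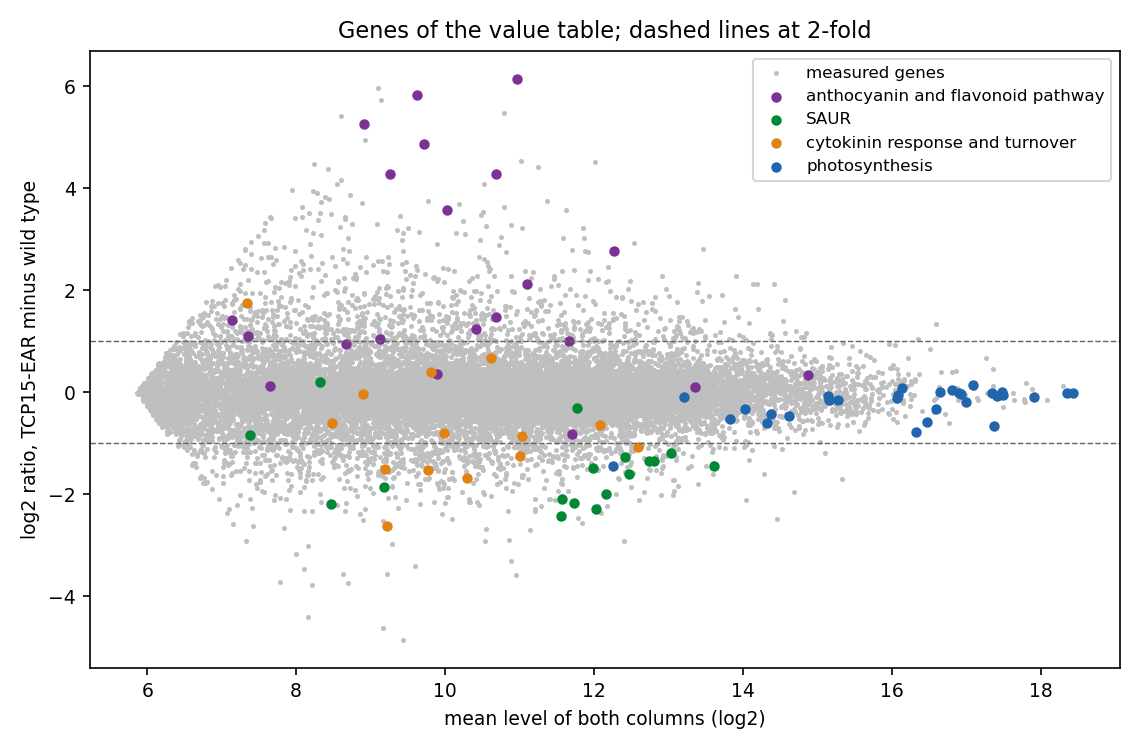
Log2 ratio of each gene in the value table, TCP15-EAR minus wild type, against its mean level in both columns (log2), with dashed lines at 2-fold and 4 gene lists in colour. Anthocyanin and flavonoid genes reach 6.14, most SAUR and several cytokinin genes lie under the lower line, and photosynthesis genes lie near 0 at the highest levels.

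Among the lists, the anthocyanin and flavonoid pathway had the highest median in the value table, 1.42 (percentile 100), with 15 of 21 measured genes at least 2-fold higher and 0 lower. Named after their values were seen, LDOX (5.25), AT5MAT (4.86) and the regulators TT8 (4.28) and PAP1 (2.76) were among them. Touch, wound and rapid stress genes had a median of 0.92 (percentile 100), with 6 of 12 at least 2-fold higher, led by the zinc finger genes RHL41 (2.81) and STZ (2.12). Cold, drought and abscisic acid genes had a median of 0.49 (percentile 100). Of 19 measured, 6 were at least 2-fold higher, led by the cold regulators CBF1 and CBF2 (3.26), and LTI30 was lower (-1.88). Senescence genes had a median of 0.75 (percentile 100), with 6 of 13 at least 2-fold higher, NAC6 (2.18) and SAG21 (1.91) foremost. Salicylic acid and defence genes had a median of 0.29 (percentile 99.9). PR1, a pathogenesis-related gene, was 62.7-fold higher from a wild-type level of 6.11, little above the background level of 5.84. WRKY38 was at 1.39, whereas PBS3 (-1.64) and SAG13 (-1.49) were lower.

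SAUR genes had the lowest median, -1.48 (percentile 0). Other hormone lists lay below the random lists as well. Cytokinin response and turnover genes had a median of -0.82 (percentile 0), with 6 of 14 at least 2-fold lower. CKX4, a cytokinin oxidase, was at -2.62 and the response regulator ARR7 at -1.67, while CKX3 was higher (1.76). Auxin response genes had a median of -0.63 (percentile 0), with IAA6 (-2.57) and IAA19 (-2.34) lowest and GH3.3 (1.37) and IAA29 (1.22) highest. Jasmonate genes had a median of -0.56 (percentile 0), with 8 of 25 at least 2-fold lower, including CYP94B3, which inactivates jasmonoyl-isoleucine (-3.40), and VSP1. JMT (1.32) and PDF1.2 (1.31) were higher. Cell wall loosening genes had a median of -0.69 (percentile 0), with 9 of 19 at least 2-fold lower, EXPA8 (-2.23) and XTH17 (-1.94) foremost, although XTH15 was far higher.

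**Figure D3:**
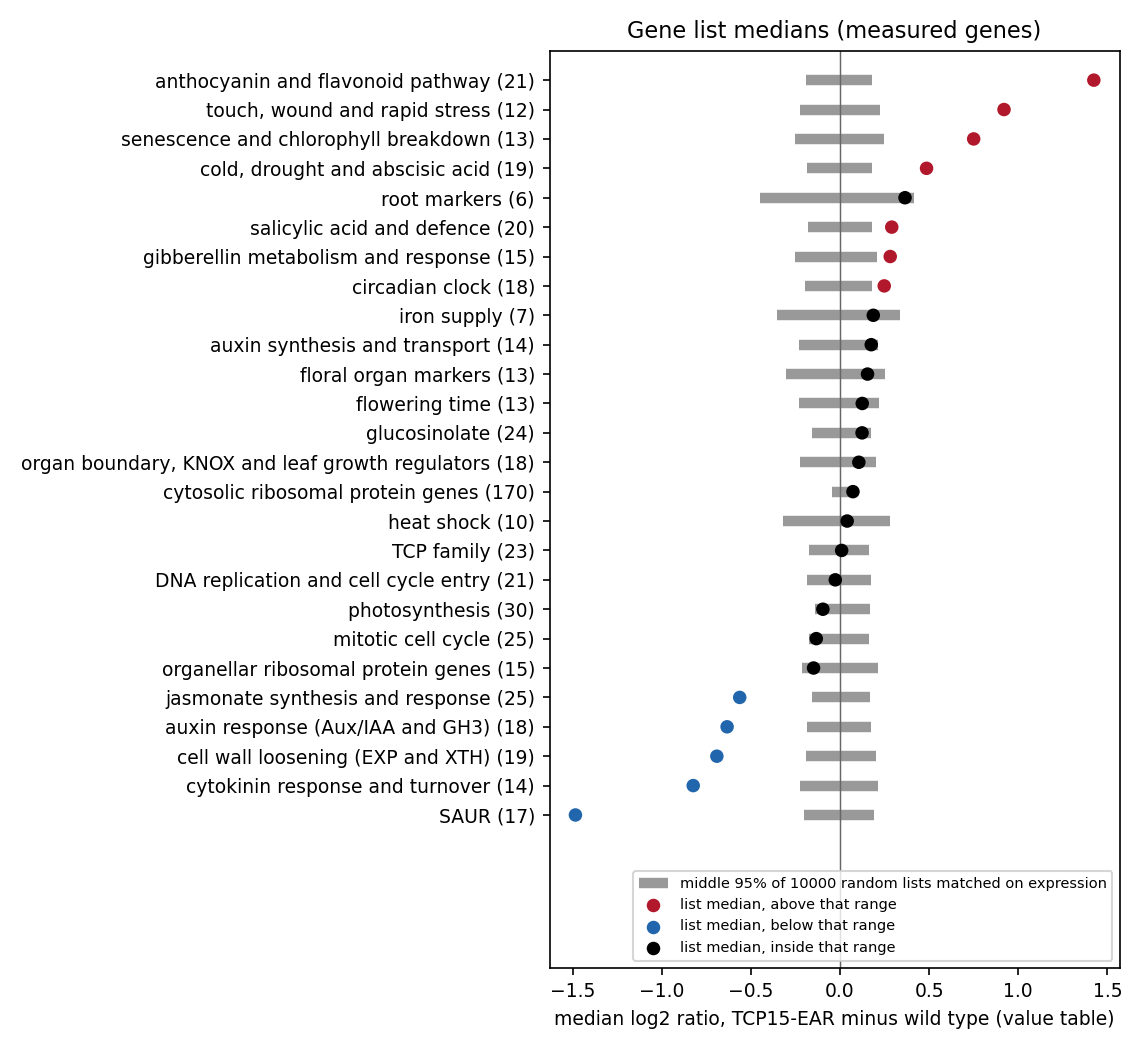
Median log2 ratio of each gene list in the value table, TCP15-EAR minus wild type (points, with the number of measured genes in brackets), and the middle 95% of medians of 10000 random lists of the same size matched on expression (grey bars). The anthocyanin list lies highest at 1.42 and SAUR lowest at -1.48, and the cell cycle, photosynthesis and TCP family lists lie inside their bars.

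Gibberellin genes (median 0.28, percentile 99.3) and circadian clock genes (0.25, percentile 99.5) lay above the random lists by less, and both fell inside the range when only brighter probes were kept. GA20OX3, a gibberellin synthesis gene, was 2.46-fold higher, with GA3OX1 at -1.29 and the clock gene ELF4 at 1.23. Lists inside the range still held genes with large ratios. BRC1, which represses branch outgrowth, was at 2.52 in the TCP family (median 0.0094, percentile 53.2), and the boundary genes CUC2 and CUC1 were at 1.87 and 1.27 (list median 0.11, percentile 85.1). The auxin synthesis gene YUC4 was at 3.51, with YUC5 at -1.21 and PIN7 at -1.14 (list median 0.18, percentile 94.9).

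Cell division genes showed small ratios in the value table. Mitotic genes had a median of -0.13 (percentile 6.27), with 0 of 25 passing 2-fold and CYCA2;1 (0.89) and CYCA2;4 (0.59) farthest from 0. DNA replication genes had a median of -0.026 (percentile 36.2), with MCM2 at -0.84 and CYCD3;3 at 0.81. Cytosolic ribosomal protein genes, known to carry class I TCP sites in their promoters, had a median of 0.073 over 170 genes (percentile 96.3) and organellar ones -0.15 over 15 (percentile 6.83). In photosynthesis (percentile 6.79), LHCB4.3 at -1.45 was the sole gene past 2-fold. Glucosinolate genes had a median of 0.12 (percentile 90.9), with IMS2 (1.13), CYP83B1 (1.12) and ESP (-2.09). Heat shock genes were at 0.040 (percentile 65.1), with AT1G53540 (1.76) and DREB2A (1.75), flowering time genes at 0.12 (percentile 86.7), with SPL4 (1.45) and SPL3 (-1.04), and iron supply genes at 0.19 (percentile 88.1), with BHLH101 (1.37).

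Floral organ markers had a median of 0.15 over 13 genes in the value table (percentile 90.6), yet 4 were at least 2-fold higher in TCP15-EAR and 1 lower. STK, an ovule identity gene, was at 3.78 and SEP3 at 2.52, while PI was lower (-1.19). Root markers had a median of 0.36 over 6 genes (percentile 96.3), of which WOX5 at 1.79 and PYK10 at 1.18 were at least 2-fold higher. The TCP15-EAR column flattens at low signal, and whether the wild-type column does so could not be examined. This limits ratios with a low wild-type level, such as those of CKX3 (level 6.47), STK (6.55), YUC4 (6.57) and UF3GT (6.72).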

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

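The settings for the scanner files and the use of the value table in their place were planned, while those within the value table and the TCP15 value without the expressed sequence tag were chosen after the data were seen. No paired analysis was possible because each genotype has 1 array. In the scanner files, other normalizations left the counts within 1.5 times those reported, but normexp correction moved 32 of 49 named gene ratios by more than the scanner's error and quantile normalization 18. Of 30 list medians the stricter filter moved 15 by at least the SD of the random medians, quantile normalization 10, loess 8 and no filter 7. Without a filter on dim probes 4802 of 26162 genes were lower, and with the stricter filter 1372 of 12205 were higher and 927 lower. The share of higher genes changed little, from 12.5% in the main setting to 13.4% without a filter and 11.2% with the stricter filter. The share of lower genes moved more, from 14.3% to 18.4% without a filter and 7.6% with the stricter filter. The brightest probe and the stricter filter each gave TCP15 1.27, and leaving out the expressed sequence tag 0.17.

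The value table on the same probes changed most: 1173 genes were higher and 863 lower, with 8 lists above and 5 below the random lists. List medians changed sign for SAUR (-1.54), organ boundary and KNOX genes (0.11), photosynthesis (-0.10), flowering time (0.18), floral organ markers (0.086), root markers (-0.036, though 0.36 in the table's own comparison) and cytosolic (0.074) and organellar (-0.15) ribosomal proteins. So did AT3G49540 (2.13), SAG12 (3.01), MIF2 (2.97), AP3 (0.15), AT1G10770 (1.503), RbcX1 (-0.27), AT1G49500 (-0.094), LHB1B1 (-0.15), IGMT4 (-0.22), GS2 (-0.38), SAUR24 (-1.27), SAUR23 (-1.20), CKX4 (-2.62), CKX3 (1.76), AT5G08330 (-0.67), LHCA2 (-0.027) and SAG29 (0.75). The cause was not tested here beyond the comparison of file and column.

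Within the value table, the stricter filter left 376 genes higher and 354 lower. Fewer genes were counted, and the shares fell too. They went from 4.84% to 3.18% for higher genes and from 4.17% to 2.99% for lower ones. The table's lists above the random lists numbered 6 to 8 and those below 5 under every alternative run, and no list or named gene still measured was reversed. Of 97 named gene ratios, the stricter filter left 57 the same and moved 4, and the rest were no longer measured. It also moved 10 of the table's 30 list medians. Gibberellin genes fell inside the range under 3 settings and the circadian clock under 1. Signal near background limits genes with only a bound, 503 and 1587 in the scanner files and 619 and 586 in the table.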

Other observations

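All tests of explanations in this part were chosen after the results were seen, and so were the gene lists marked as added.

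Gene families were taken from the probe descriptions, and some share genes with the fixed lists. In the value table, 56 families had at least 15 measured genes, and 8 lay above and 7 below the random lists. By construction 5% of lists of genes drawn at random lie outside. Genes of a family are not drawn at random, so this 5% is no yardstick for the number of families outside. ABC transporters had the highest median log2 ratio, 0.66, with 7 of 23 at least 2-fold higher, and MATE efflux carriers had a median of 0.26 over 26 genes. Pectate lyases, which cut pectin in cell walls, had a median of -0.79 with 6 of 15 at least 2-fold lower. Glutaredoxins had a median of -0.31 over 31 genes and invertase or pectin methylesterase inhibitors -0.40 over 16. The family described as auxin-responsive lay inside the range, with a median of 0.057 over 28 genes, 5 at least 2-fold higher and 8 lower; it includes SAUR genes such as AT1G29450.

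The list of tapetum and pollen wall genes (added) was made after such genes had been seen among the largest bounds. Of its 17 genes, 7 were measured in the value table, 2 of them at least 2-fold lower in TCP15-EAR and 1 above 0. Their median was -0.67, at percentile 0.31, with LAP5 at -3.77 and CYP704B1 at -2.00, while DRL1 (AT4G35420) was at 0.079; with the stricter filter on dim probes the list lay inside the random range. ACOS5 and CYP703A2 were brighter in wild type by at least 8.51-fold and 6.94-fold, as was MEE48 by at least 9.38-fold. Late pollen genes (added) were at background in the table: 0 of 11 were measured in both columns. In the scanner files all 11 were bright only on the array labelled wild type, GRP17 by at least 3207-fold.

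The disagreement between the wild-type scanner file and the wild-type column was weighed against 3 explanations. Another signal or normalization would keep the ranks of probes, yet the highest rank correlation with any signal tried was 0.917. A swap of the files of both genotypes would tie the TCP15-EAR column to the scanner file labelled wild type, and that correlation was at most 0.919. A candidate explanation is that file and column come from different arrays, that of the file from tissue with flowers: floral organ markers were 4.72 (log2) higher in the file than in the column. The column also ranked closer to the TCP15-EAR scanner file (0.976) than to its own. Its floral level of -3.51 lay near the -3.45 of the TCP15-EAR file, whereas its own file was at 1.205. In flower signal the column thus resembled the TCP15-EAR rosette array and the file did not. Which of them holds the labelled rosette, or whether both do with different shares of inflorescence, stays open, as each is 1 array.

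The gap between TCP15 probes in the value table exceeded ordinary disagreement between probes, at the 99.9th percentile of genes with several measured probes, whose median gap was 0.15. The upstream probe was higher and the downstream probe lower, 3.26 (log2) apart, which may reflect a transcript that holds the upstream part without the native 3′ end, as a transgene could make, together with less native transcript. Whether the transgene holds the whole sequence of the upstream probe was not settled. Cross-hybridization of either probe and a wild-type column from another array were not tested, so this remains a hypothesis.

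CBF1 (3.47), CBF2 (3.26), DREB1A (2.38) and RHL41 (2.81) were higher in TCP15-EAR in the value table. Cold lasting many hours would raise the targets of CBF proteins together, but the 7 added targets had a median of 0.17 with an SD of 0.53 between them. Shorter or milder cold stays open, as 6 of the 7 were above 0 with KIN2 at 1.04, and so does handling, as 11 of 12 touch, wound and rapid stress genes were above 0. A different time of day at harvest stays open too. Evening clock genes (median 0.69) lay 0.66 above morning ones (0.028), more than the 0.45 that 95% of pairs of random lists stay under. Clock genes are not drawn at random, so this gap cannot decide it. The gap came from the evening genes, since morning ones lay inside the range (percentile 56.4). An effect of TCP15-EAR on the CBF, stress and clock genes stays open, as 1 harvest per genotype confounds genotype with harvest.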
